A study of Mus musculus with 18 samples.

How the data were processed

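Whole livers of C57BL/6J mice were flushed with saline before RNA isolation, and libraries were made with a poly(A)-selecting kit, per the labels' protocols. The series design text gives 30 mice, while the groups it lists sum to 18 and the labels hold 18 libraries (6 ad libitum controls and 3 in each of the 4 other groups). The labels describe the libraries as separate, and name no batch, sex or time of collection. Reads were aligned with HISAT2 2.0.5 to the mm10 build, per the submitters' processing notes. The gene counter, its strand setting and the annotation are not given in the sources used here.

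The values come from 1 table of the authors' own comparisons over 12019 genes. Per the file headers it holds a normalized signal for each group, which the values show to be a group mean of gene counts divided by size factors, made with DESeq2 by the authors, as the name of the table states. It also holds, per the file headers, an adjusted p-value and a log2 fold change against the control for each of the 4 interventions; the deposited log2 fold changes lay close to the log2 ratio of the group means. Which genes DESeq2 gave no adjusted p was taken as the authors left it. A further deposited log2 fold change column is headed TM5441, a compound that none of the labels names. Another table gives normalized values for 18 columns whose names match none of the labels, so that no column could be given a sample, and none of these values was used. The tests planned before the data were examined, limma on values per library among them, were therefore replaced by the authors' adjusted p, and no SD, standard error or test between interventions was computed. The smallest group means above 0 take 3 distinct values under 0.5 in each of the 5 group columns, as means over 3 libraries with a single read in 1 of them would. This holds for the control too, for which the labels list 6 libraries. Its values, 0.315 to 0.350, are of the size of those in the 4 groups of 3 libraries (0.299 to 0.398). This argues against a control mean over 6 libraries, and which libraries stand behind that mean is not known. The depth of each library is likewise unknown, and the spread that the authors' adjusted p rests on is that between these libraries.

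Gene symbols are those of the table. Of these 10901 match a symbol of GENCODE vM21, older symbols were matched through RefSeq synonyms that belong to a single gene, and 18 names had been turned into dates by a spreadsheet and are not named. One gene is at 0 in all groups. Coordinates are those of the annotation for the mm10 assembly. Hsd3b5 lies on chromosome 3 from 98618634 to 98630252, Fasn on chromosome 11 from 120805846 to 120824547, Dbp on chromosome 7 from 45705088 to 45710203, Saa1 on chromosome 7 from 46740497 to 46742980, and Creld2 on chromosome 15 from 88819646 to 88826683; all are protein-coding, and their values cover the whole gene.

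A gene was called changed at an adjusted p under 0.05 in the authors' table. Gene lists and cell type markers, fixed before the data were examined, were described by the number of members called in each direction and tested against all other genes with limma 3.58.1 (cameraPR on ranks of the log2 fold changes, R 4.3.3). The correlation between genes was preset at 0.01, since it could not be estimated without values per library, and a preset of 0.05 was the alternative. The p-values of this test compare genes with genes and do not measure variation between mice. A list could therefore pass through a few genes that differ together in 1 mouse. This test used the 11201 genes with a mean of at least 10 over the groups, lists with at least 3 such genes, and Benjamini-Hochberg adjustment over the 35 lists of a comparison. Counts adjusted over the list alone need unadjusted p-values and were not made. The 13 mitochondrially encoded transcripts of 1 list are not in the table. Markers of T and NK cells and of B and plasma cells had too few genes at that level for a test. For the 3 compounds most of them have no adjusted p, so that they say nothing about these cells there. Under caloric restriction 2 of 6 T and NK markers and 6 of 7 B and plasma markers have an adjusted p, and none passed. Median log2 fold changes of lists cover members with a mean of at least 10. In 40 simulations per shift made from the log2 fold changes of caloric restriction, shuffled within bins of expression, the set test found 62.5% of lists shifted by 0.3, 93.8% of those shifted by 0.6 and all shifted by 1, and called 1.38% of unshifted lists; the share found at 0.3 was 96.2% for rapamycin, 97.5% for TM5614 and 100% for metformin, with 3.71%, 4.05% and 3.02% of unshifted lists called. The shuffling removes any correlation between genes, so more unshifted lists would be called where genes move together.

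The genes named are, by a rule fixed before the data were examined, the 6 largest rises and 6 largest falls among called genes whose higher group mean was at least 50, up to 4 members of each list with the smallest adjusted p, and a fixed set of genes for every comparison (among them Fkbp1a, Mtor, Fgf21, Igf1, Pck1, Cpt1a, Srebf1, Fasn, Cyp7a1 and Cdkn1a). Some genes that this rule selects are not reported here. The part of the rule that asks for treated libraries beyond all control libraries could not be applied. Other genes named, such as those behind counts of 5 or fewer, those shared between comparisons and the 11 clock genes plotted, were chosen after their values were seen. A log2 value against the other 3 treated groups is the log2 of a group mean plus 1 minus the average of the same for the other 3. Correlations of log2 fold changes and the correlation of simulated unchanged groups (200000 genes) were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Alternatives were other thresholds, level filters and pseudocounts of 0.5, 1 and 5 on the group means, the other preset correlation, and references other than the control.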

Results

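Liver RNA was sequenced from C57BL/6J mice after 8 weeks of 1 of 4 interventions that began at 21 weeks of age, or of free feeding. The labels list 18 libraries: 6 from mice fed ad libitum, the control, and 3 each from mice under 30% caloric restriction, rapamycin at 42 mg/kg/day, metformin at 37.5 mg/kg/day and TM5614 at 20 mg/kg/day, with the compounds mixed into the chow. Rapamycin inhibits the kinase mTOR through its binding protein FKBP12 and metformin is a glucose-lowering biguanide. The values are the group means, log2 fold changes against the control and adjusted p-values of the authors' deposited table, which covers 12019 genes. The smallest control means are of the size that means over 3 libraries have, not over the 6 labelled. No value per library entered, so the spread between mice enters only through the authors' adjusted p, and no SD is given. The set tests compare genes with other genes, so their p-values hold no spread between mice.

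The first question is how far each intervention moved the liver transcriptome from that of freely fed mice. Caloric restriction raised 1145 genes and lowered 1087 of the 11760 genes with an adjusted p. TM5614 raised 218 and lowered 211 of 10834 genes, rapamycin raised 74 and lowered 70 of 10369 genes, and metformin raised 12 and lowered 6 of 7350 genes. A change of at least 1 on the log2 scale was reached by 657 of the genes called under caloric restriction, 120 under TM5614, 42 under rapamycin and 8 under metformin. These calls are those of the authors' deposited table at an adjusted p under 0.05, and the genes without an adjusted p there numbered 259 for caloric restriction, 1185 for TM5614, 1650 for rapamycin and 4669 for metformin. The differences between these counts were not tested.

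**Figure D1:**
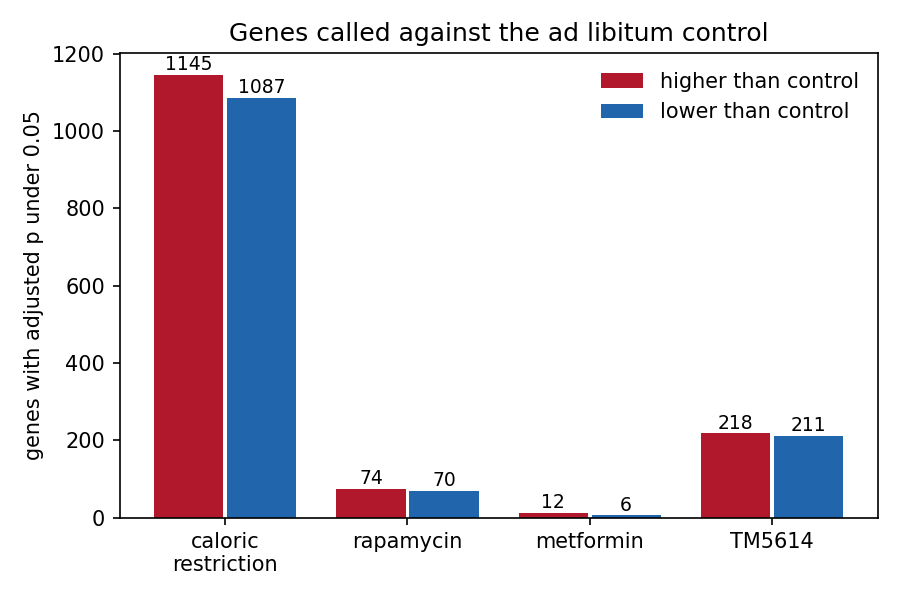
Bars give the number of genes (vertical axis) called higher or lower than the ad libitum control at an adjusted p under 0.05 in the authors' deposited table, for each intervention (horizontal axis). Caloric restriction has 1145 genes higher and 1087 lower, against 12 and 6 for metformin.

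Under caloric restriction the liver held less of most transcripts that are higher in male livers and more of transcripts that are higher in female livers. Of the 16 male-biased genes, 15 fell and 1 did not pass. The authors' deposited table gives Hsd3b5, a keto-steroid reductase, a mean of 968 normalized counts in the control and 6.80 under restriction (log2 fold change -7.17, adjusted p = 2.09e-49). Falls of the same kind stand in the authors' deposited table for Selenbp2 (-6.35), Nudt7 (-3.23) and the organic anion carrier Slco1a1 (-2.89). Of the 16 female-biased genes in the table, 10 rose, none fell and 5 did not pass, with no adjusted p for 1. The flavin monooxygenase Fmo2 went from 48.6 to 1261 normalized counts in the authors' deposited table (log2 fold change 4.70, adjusted p = 2.45e-42), and the acyl-CoA thioesterase Acot3 from 19.9 to 1066. The transcription factor Cux2 reached 164 normalized counts from a control mean of 1.0 in the authors' deposited table, so that the size of its fold rests on a control value near 0. In limma's rank-based set test the male-biased list had an adjusted p of 9.28e-09 (median log2 fold change -2.82) and the female-biased list one of 1.50e-06 (median 2.74 over members that passed the level filter). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, given as values, had log2 fold changes of 0.10, -0.06, -0.40 and -0.14 in the authors' deposited table.

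The largest rises also held Cyp2b9 (5.80), a female-biased cytochrome P450, and Cyp2c69 (4.99) in the authors' deposited table. Among the falls, the fatty acid elongase Elovl3 (-5.23) and the protease inhibitor Serpina1e (-4.66) stood beside Hsd3b5 and Selenbp2 in the authors' deposited table. Mup17, a major urinary protein, is listed at 0 under restriction and at 64.2 in the control in the authors' deposited table, a control mean that is a whole multiple of 1 read of a single control library. Cyp2c69, Serpina1e and Mup17 belong to families of near-identical copies, so the division of reads among the copies is uncertain. Cela2a, a pancreatic protease, had a control mean of 75.4 and a mean of 3.43 under restriction in the authors' deposited table (adjusted p = 0.00305), and its mean was also low in the other 3 treated groups.

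**Figure D2:**
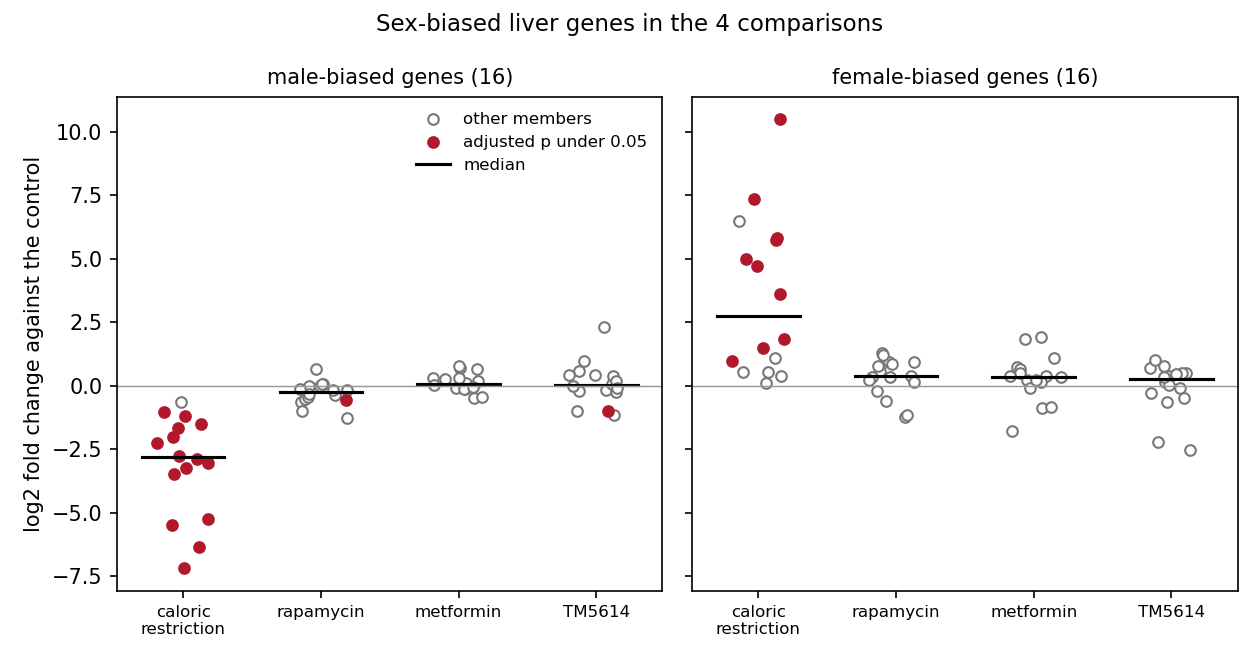
Each point is the log2 fold change (vertical axis) of 1 male-biased (left) or female-biased (right) gene against the control in the authors' deposited table, by intervention (horizontal axis); filled points have an adjusted p under 0.05, and lines are medians of the points. Under caloric restriction 15 of 16 male-biased genes lie lower and 10 of 16 female-biased genes lie higher with such a p.

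Lipid synthesis genes were lower as sets and fatty acid oxidation genes higher as a set under caloric restriction. Of 19 fatty acid and triglyceride synthesis genes, 10 fell, 2 rose (Dgat2 and Fads2) and 7 did not pass (set test adjusted p = 0.00343). ATP citrate lyase (Acly) had a log2 fold change of -1.78, adjusted p = 5.25e-22, in the authors' deposited table, where fatty acid synthase (Fasn) had -2.10, adjusted p = 1.26e-16. Elovl5 and Me1 followed with -1.67 and -1.37 in the authors' deposited table. Of 24 cholesterol synthesis and uptake genes, 7 fell and 17 did not pass (set test adjusted p = 8.88e-04), with Sc5d at -1.36, Dhcr7 at -1.22, Nsdhl at -0.65 and Fdps at -0.95 in the authors' deposited table. The regulator Srebf1 (-0.66, adjusted p = 0.0927) did not pass in the authors' deposited table. Of 25 fatty acid oxidation and ketogenesis genes, 12 rose, 2 fell (Acaa1b and Bdh1) and 11 did not pass (set test adjusted p = 8.63e-04). The fatty acid hydroxylases Cyp4a10 and Cyp4a14 rose by 2.54 and 2.46 on the log2 scale in the authors' deposited table, the thioesterases Acot1 and Acot2 by 2.12 and 2.81. Cpt1a, which admits fatty acids to mitochondria, had 0.87, adjusted p = 5.74e-06, in the authors' deposited table, and the fasting hormone Fgf21 went from 13.3 to 49.8 normalized counts with an adjusted p of 0.0497, just under the threshold.

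**Figure D3:**
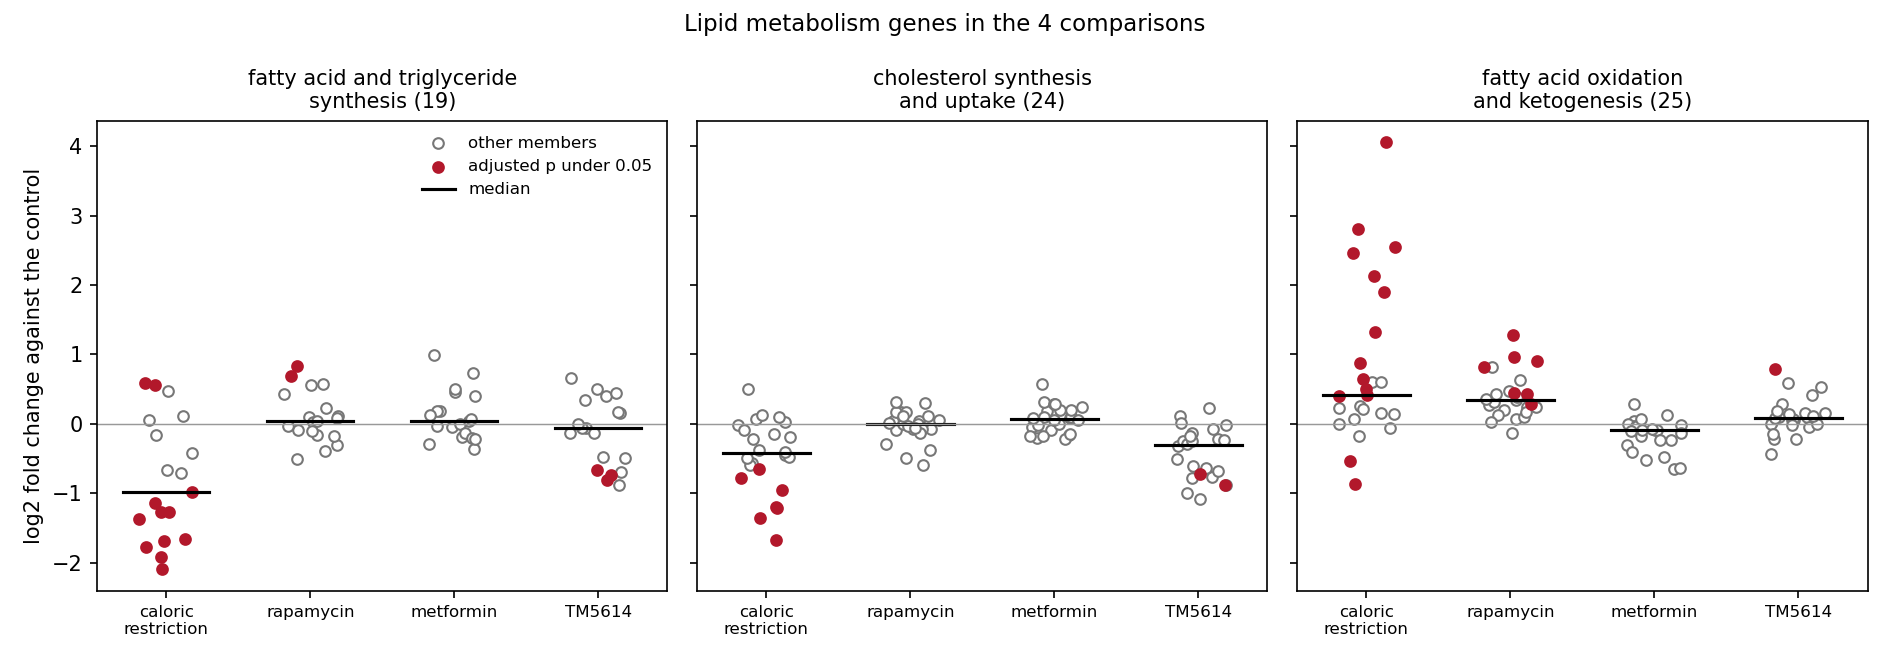
Each point is the log2 fold change (vertical axis) of 1 gene of a lipid metabolism list against the control in the authors' deposited table, by intervention (horizontal axis); filled points have an adjusted p under 0.05, and lines are medians of the points. Under caloric restriction 10 of 19 synthesis genes lie lower and 12 of 25 oxidation genes lie higher with such a p.

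Gluconeogenesis genes were higher as a set under caloric restriction. Of 15 gluconeogenesis genes 6 rose and 9 did not pass (set test adjusted p = 0.00215). Gpt had 0.58 and Foxo1 0.75 in the authors' deposited table, where Pck1, an enzyme of the pathway, had 0.43, adjusted p = 0.355. Of 25 drug metabolism genes 13 rose, 4 fell (Cyp2c55, Gstm1, Cyp2c29 and Ephx1) and 8 did not pass (set test adjusted p = 0.00594, and adjusted p = 0.0562 with the correlation between genes preset at 0.05). Ugt1a1 rose by 1.15, the efflux pump Abcb1a by 3.37, Cyp2a5 by 3.39 and the P450 reductase Por by 2.45 on the log2 scale in the authors' deposited table. The 28 amino acid breakdown and urea cycle genes split into 10 that rose and 4 that fell (set test adjusted p = 0.0631), with Cbs at -1.20, adjusted p = 4.36e-41, in the authors' deposited table. The 19 bile acid genes split into 5 and 5 (set test adjusted p = 0.462), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.21, adjusted p = 0.904, in the authors' deposited table. Of 20 hepatokine and energy sensing genes 7 rose, 1 fell (Enho) and 12 did not pass (set test adjusted p = 0.00344), led by Nampt at 2.03 in the authors' deposited table. Igf1 had a log2 fold change of 0.52, adjusted p = 6.70e-04, in the authors' deposited table, in a growth hormone list of 13 genes with 2 rises and 1 fall (set test adjusted p = 0.339).

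Clock genes were higher as a set under caloric restriction, and interferon and macrophage genes were lower as sets. Of 19 clock genes 9 rose, 1 fell and 9 did not pass (set test adjusted p = 4.17e-04). The authors' deposited table gives log2 fold changes of 2.08 for Cry1, 1.64 for Cry2 and 2.51 for Per2, and of -1.23 for Nr1d1. Of 27 interferon response genes 8 fell and 19 did not pass (set test adjusted p = 3.08e-06), with Oasl1 at -1.91, Bst2 at -0.73 and Psmb9 at -1.33 in the authors' deposited table. Of 12 Kupffer cell and macrophage markers 4 fell and 7 did not pass, with no adjusted p for 1 (set test adjusted p = 2.17e-05); the complement genes C1qa, C1qb and C1qc had -0.80, -0.92 and -0.97 in the authors' deposited table and Cd5l had -1.33. The lower macrophage markers thus stand beside the lower interferon genes, some of which macrophages also express. Pericentral hepatocyte markers held 4 rises among 10 genes (set test adjusted p = 0.0492, and adjusted p = 0.119 with the correlation preset at 0.05), with Slc1a2 at 1.43 and Cyp2e1 at 0.99 in the authors' deposited table.

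In the unfolded protein and heat shock list, 5 genes rose and 6 fell under caloric restriction (set test adjusted p = 0.714). The members that fell were chaperones of the endoplasmic reticulum, among them Pdia6 (-1.20), Calr (-1.21), Sdf2l1 (-2.51) and Pdia4 (-1.04) in the authors' deposited table. The members that rose were Dnajb9, of the endoplasmic reticulum, and the cytosolic heat shock genes Hspa8, Hsph1, Hspb1 and Hspa1b. The autophagy and lysosome list held 7 rises and 3 falls among 29 genes (set test adjusted p = 0.293), the ATF4 list 3 rises and 1 fall among 21 (adjusted p = 0.107), and the NRF2 list 4 rises and 3 falls among 16 (adjusted p = 0.634). None of the 62 ribosomal protein genes passed (set test adjusted p = 0.0492, and 0.267 with the correlation preset at 0.05), nor any of the 36 complex I genes (adjusted p = 0.875). In the acute phase list 3 genes rose and 2 fell (adjusted p = 0.975), in the coagulation list 5 rose and 2 fell (adjusted p = 0.776), and in the glycolysis list 1 rose and 2 fell (adjusted p = 0.564). Of 17 cell cycle genes Mcm3 and Mcm5 fell (adjusted p = 0.0492, and 0.124 at 0.05), of 22 senescence genes Trp53 fell (adjusted p = 0.714), and of 23 matrix genes Timp3 rose (adjusted p = 0.857). Fkbp1a and Mtor, whose products rapamycin acts on, had -0.32, adjusted p = 0.00860 and -0.40, adjusted p = 0.0317, respectively, in the authors' deposited table. Cdkn1a (1.32, adjusted p = 0.123) did not pass in the authors' deposited table.

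Fatty acid oxidation and acute phase genes were higher as sets under rapamycin, and sinusoidal endothelial markers were lower as a set. Of 25 fatty acid oxidation genes 7 rose and 17 did not pass, with no adjusted p for 1 (set test adjusted p = 1.85e-06, median log2 fold change 0.34), with Hadha at 0.29, Cyp4a14 at 1.28 and Slc25a20 at 0.45 in the authors' deposited table. Of 22 acute phase genes, which the liver secretes or induces in inflammation, 2 passed and the set test gave an adjusted p of 1.93e-06 (median 0.54). Lipocalin 2 (Lcn2) had means of 79.3 in the control and 981 under rapamycin in the authors' deposited table (log2 fold change 3.63, adjusted p = 0.0388), and Steap4 had 1.94. The largest rises also held Nfkbiz (3.03), Pim1 (2.55) and Irf1 (2.29), genes induced by cytokines, and the P450 gene Cyp2c40 (1.73) in the authors' deposited table. Of 10 sinusoidal endothelial markers the scavenger receptors Stab1 (-0.72) and Stab2 (-0.90) fell in the authors' deposited table (set test adjusted p = 1.58e-04).

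The largest falls under rapamycin held the clock output gene Dbp, from 177 to 34.2 normalized counts in the authors' deposited table (log2 fold change -2.37, adjusted p = 0.00787), Clec2h (-1.93), the peptide hormone gene Enho (-1.81) and Spata2l (-1.78). Dmbt1 is listed at 0 under rapamycin and at 96.4 in the control in the authors' deposited table, a control mean that is a whole multiple of 1 read of a single control library. Dbp was the 1 clock gene of 19 that passed (set test adjusted p = 0.218). Extracellular matrix genes were lower as a set with 1 member past the threshold, Lum (set test adjusted p = 8.77e-05, median -0.42), and pericentral markers with none of 10 (adjusted p = 0.00105, median -0.38). The senescence and p53 list was higher as a set with no member past the threshold and no adjusted p for 6 of 22 (set test adjusted p = 2.74e-04, median 0.25), Cdkn1a having 1.96, adjusted p = 0.0784, in the authors' deposited table. Neutrophil markers, 4 in the table of which 2 have an adjusted p and neither passed, were higher as a set (adjusted p = 0.00537, median 0.61), and the NRF2 list with Gsr alone past it (adjusted p = 0.00408, median 0.24). Among drug metabolism genes Gstm1 (0.58), Ephx1 (0.54) and Gstm3 (0.77) rose and Ugt1a1 (-0.34) fell in the authors' deposited table (set test adjusted p = 0.0608). Scd1 and Me1 rose in a lipid synthesis list with a set test adjusted p of 0.698. Igfbp2 fell (-1.13, adjusted p = 8.01e-04, in the authors' deposited table).

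The targets of the compound, Mtor (0.41, adjusted p = 0.116) and Fkbp1a (0.19, adjusted p = 0.417), did not pass under rapamycin in the authors' deposited table. The same holds for Fasn (-0.31), Srebf1 (-0.50), Pck1 (-0.10), Cpt1a (0.28), Igf1 (0.22) and Cyp7a1 (-0.73) in the authors' deposited table, which gives no adjusted p for Fgf21 (0.39). The set tests for male-biased genes (adjusted p = 0.0151), the unfolded protein list (adjusted p = 0.0151) and amino acid breakdown (adjusted p = 0.0386) passed with the correlation preset at 0.01 and not at 0.05, where the adjusted p were 0.0661, 0.0773 and 0.148. The same held for glycolysis (adjusted p = 0.0461 and 0.137), coagulation (0.0386 and 0.137), cell cycle (0.0386 and 0.114; no adjusted p for 8 of 17 genes), erythroid markers (0.0386 and 0.0679) and stellate cell markers (0.0221 and 0.0661). Macrophage markers were lower as a set with no member past the threshold and no adjusted p for 1 of 12 (set test adjusted p = 0.00315, median -0.29).

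Metformin raised 4 genes of the unfolded protein response, and its libraries held more reads assigned to the ribosomal RNA precursor. Of 22 unfolded protein and heat shock genes 4 rose, none fell and 16 did not pass, with no adjusted p for 2 (set test adjusted p = 7.82e-05, median 0.35). The median of this list was 0.12 against the other 3 treated groups, and 0.18 under rapamycin and 0.22 under TM5614 against the control. Creld2 had means of 208 and 836 in the control and under metformin in the authors' deposited table (adjusted p = 1.26e-04), and Manf had 1.09, the chaperone Hspa5 1.07 and Hyou1 0.98. Rn45s, the ribosomal RNA precursor, which poly(A) selection should remove so that its level depends on library preparation, went from 17687 to 366479 normalized counts in the authors' deposited table (log2 fold change 4.37, adjusted p = 0.00561). Rn45s made up 4.4% of the summed means under metformin, 0.555% under rapamycin, 0.472% under caloric restriction, 0.227% in the control and 0.132% under TM5614. Lars2 had 4.58, adjusted p = 0.00295, in the authors' deposited table, and its shares went with those of Rn45s (0.261%, 0.0298%, 0.0306%, 0.0117% and 0.00809% in the same order), so that the 2 are not taken as separate changes. The other raised genes were Mlec (0.63), Sec23b (0.60), Gmppb (0.87) and Cad (0.87) in the authors' deposited table, and 1810074P20Rik. The acute phase gene Saa1 rose (3.45, adjusted p = 0.0121, in the authors' deposited table), as 1 of 22 members of its list (set test adjusted p = 1.72e-04, median 0.36).

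The genes lowered by metformin held Setdb2 (-1.21), Srf (-1.10), Lpin2 (-0.99), Foxo1 (-0.80) and Agxt (-0.44) in the authors' deposited table. Foxo1, an activator of glucose production, was the 1 member of 15 gluconeogenesis genes that passed (set test adjusted p = 0.00463, median -0.42), Pck1 having -0.50, adjusted p = 0.888, in the authors' deposited table. Macrophage, sinusoidal endothelial and neutrophil markers were lower as sets (adjusted p = 1.48e-04, 0.00463 and 0.00637, with medians of -0.38, -0.41 and -0.81). None of them was called, but 5 of 12 macrophage markers, 1 of 10 endothelial markers and all 4 neutrophil markers have no adjusted p for metformin. Ribosomal protein genes were higher as a set by a median of 0.13 with no member past the threshold among the 59 that have an adjusted p (set test adjusted p = 1.48e-04). The set test also passed for fatty acid oxidation (adjusted p = 0.0122, median -0.10) and complex I (adjusted p = 0.0116, median 0.10), and not with the correlation preset at 0.05 (adjusted p = 0.0986 and 0.107). The ATF4 list (adjusted p = 0.0193, and 0.107 at 0.05) and stellate cell markers (adjusted p = 0.0142, and 0.0535 at 0.05) were lower as sets, with no adjusted p for 11 of 21 and 6 of 10 members and no call among the others. Igf1 (0.24), Cpt1a (-0.10), Srebf1 (-0.04), Fasn (0.19), Cyp7a1 (0.21), Cdkn1a (-0.94), Mtor (0.22) and Fkbp1a (0.00) did not pass in the authors' deposited table, which gives no adjusted p for Fgf21 (-0.40).

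TM5614 raised acute phase genes and 4 clock genes, and cholesterol synthesis genes were lower as a set. Of 22 acute phase genes 5 rose, none fell and 17 did not pass (set test adjusted p = 1.44e-06, median 0.52). Serum amyloid Saa1 went from 696 to 6855 normalized counts in the authors' deposited table (log2 fold change 3.30, adjusted p = 0.00396) and Saa2 from 450.4 to 5777, while Steap4 had 2.05, Saa4 1.35 and Lcn2 3.23. Of 19 clock genes Per3 (2.06), Dbp (1.86), Per2 (1.17) and Tef (1.17) rose and 15 did not pass in the authors' deposited table (set test adjusted p = 0.243). Of 28 amino acid breakdown genes 6 fell, none rose and 22 did not pass (set test adjusted p = 0.0762), with Agxt at -0.85, adjusted p = 1.22e-11, in the authors' deposited table, and Cbs at -0.44, Hal at -0.78 and Cth at -0.80.

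**Figure D4:**
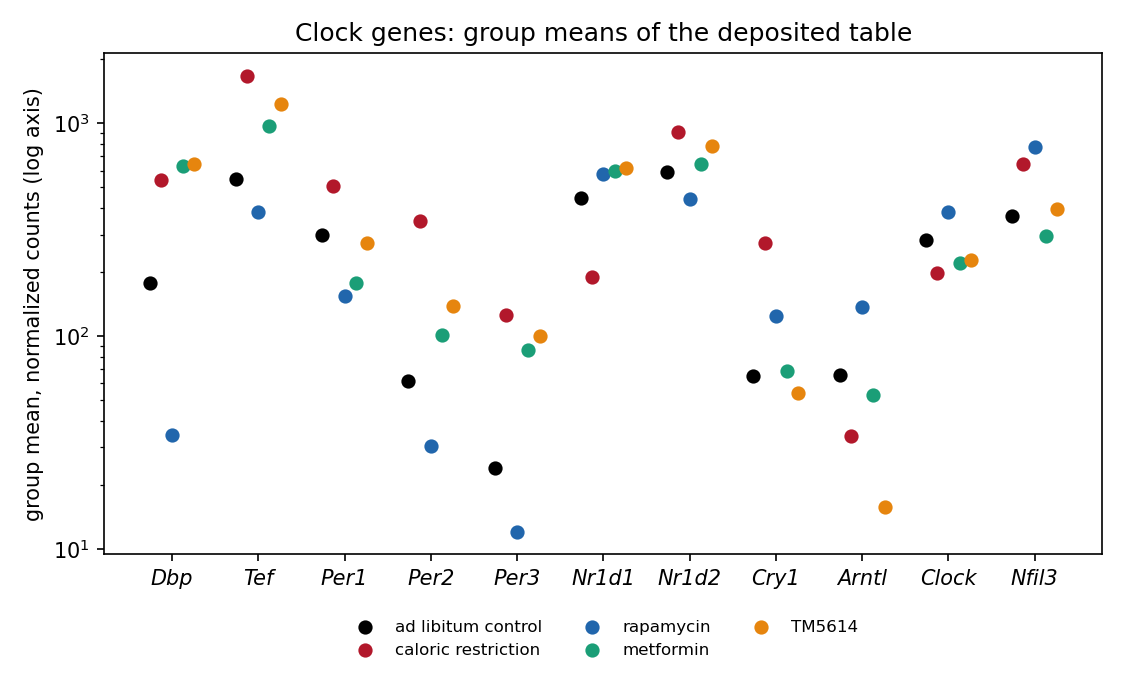
Points are the authors' group means in normalized counts (vertical axis, log scale) of 11 clock genes (horizontal axis) in the 5 groups. Dbp lies at 34.2 under rapamycin, 177 in the control and 644 under TM5614.

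Acly (-0.66), Elovl5 (-0.74) and Fasn (-0.82, adjusted p = 0.0216) fell in the authors' deposited table among 19 lipid synthesis genes, of which none rose (set test adjusted p = 0.705), and Srebf1 had -0.88, adjusted p = 0.0573. Cholesterol genes were lower as a set (adjusted p = 8.72e-05, median -0.31), with Sc5d (-0.73) and Mvk (-0.88) past the threshold in the authors' deposited table. Glucose-6-phosphatase (G6pc) fell from 5224 to 1439.5 normalized counts in the authors' deposited table (-1.86, adjusted p = 0.00161), the 1 of 15 gluconeogenesis genes that passed (set test adjusted p = 0.0830). Por (1.05) and Cyp2a5 (1.25) rose and Ces1d (-0.58) fell in the authors' deposited table among 25 drug metabolism genes (set test adjusted p = 0.182). The largest other rises were C4a (2.63), Scara5 (2.57) and B3galt1 (2.33), and the largest other falls Ppp1r3g (-3.55), Apold1 (-3.11), Trp53inp1 (-2.25) and Arl4d (-2.13) in the authors' deposited table. C4a is nearly identical to its neighbour C4b, so its reads are uncertain. Dmbt1, listed at 0, and Cela2a, at 2.49, fell too, with control means of 96.4 and 75.4 in the authors' deposited table.

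The fibrinolysis and coagulation list of 24 genes, 1 of them without an adjusted p, had no member past the threshold under TM5614 (set test adjusted p = 0.590). The macrophage markers were lower as a set with no member past the threshold and no adjusted p for 1 of 12 (set test adjusted p = 0.00350, median -0.35). Ribosomal protein genes were lower as a set with a median of -0.14 (adjusted p = 3.25e-04, and adjusted p = 0.0669 with the correlation preset at 0.05), and complex I genes with a median of -0.13 and Ndufs7 past the threshold (adjusted p = 0.00883, and 0.142 at 0.05). The ATF4 list had a median of -0.23, with Atf5 lower (adjusted p = 0.0248, and 0.142 at 0.05). Fgf21 (-0.15), Igf1 (0.27), Pck1 (-0.32), Cpt1a (0.41), Cyp7a1 (0.94), Cdkn1a (-0.33), Fkbp1a (-0.14) and Mtor (0.43, adjusted p = 0.0502) did not pass in the authors' deposited table.

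All 4 comparisons use the same control mean, and lists that moved the same way in several of them can reflect that mean. Macrophage markers, lower against the control in all 4 comparisons, had medians of 0.28, 0.10 and 0.16 under rapamycin, metformin and TM5614 against the other 3 treated groups, and of -0.55 under caloric restriction. For the compounds the other groups hold caloric restriction, with a median of -0.86 against the control. A fall shared by all 4 interventions would give such values too, so they cannot tell it from an effect of the control mean. Sinusoidal endothelial markers had medians of -0.36 under rapamycin and -0.22 under metformin in this way, against -0.66 and -0.41 relative to the control. Fatty acid oxidation genes under rapamycin had 0.19, cholesterol genes -0.14 under caloric restriction and -0.21 under TM5614, and male-biased genes under rapamycin 0.55, the opposite sign to their -0.24 relative to the control, with caloric restriction among the other groups. Acute phase genes had medians of 0.26, -0.04 and 0.17 in the 3 compounds against the other treated groups. Of the 429 genes called under TM5614, 234 had at least 0.5 of their size in the same direction against the other 3 treated groups, as had 1976 of 2232 under caloric restriction, 101 of 144 under rapamycin and 14 of 18 under metformin. Agxt, a glyoxylate enzyme, and Setdb2, a methyltransferase of the SET domain family, were the 2 genes called in all 4 comparisons, lower in each. Agxt had log2 fold changes of -0.65 under caloric restriction, -0.47 under rapamycin, -0.44 under metformin and -0.85 under TM5614 in the authors' deposited table.

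How far each compound moved the same genes as caloric restriction was compared next; the shared control mean by itself raises the number in the same direction and lowers that in opposite directions, and the numbers were not tested. TM5614 and caloric restriction shared 102 raised genes, among them Por, Cyp2a5, Ppara, Nampt, Per2, Per3 and Dbp. They shared 105 lowered genes, among them Fasn, Acly, Elovl5, Agxt, Cbs, Hal and Sc5d. Independent calls in the 2 comparisons would share 22.7 raised and 20.7 lowered genes. Per2, Per3 and Dbp are clock genes, and the labels give no time of collection. Times of collection or feeding that differed from those of the control could add to this overlap and to the correlation given below. In opposite directions lay 12 genes, against 43.3 for independent calls, among them Ces1d and Gnmt, raised by restriction and lowered by TM5614. Rapamycin and caloric restriction shared 22 raised genes, among them Acot1, Cyp4a10, Cyp4a14 and Slc25a20, and 18 lowered genes, among them Agxt, Enho and Nudt7. Independent calls would share 7.96 raised and 6.98 lowered genes. In opposite directions lay 26 genes, against 14.9 for independent calls. Among them, Scd1, Me1, Gstm1, Ephx1 and Hyou1 were lowered by restriction and raised by rapamycin, and Dbp, Prodh and Ugt1a1 went the other way. Metformin shared no raised gene and 2 lowered genes, Agxt and Setdb2, with caloric restriction, against 1.57 and 0.648 for independent calls. A further 7 lay in opposite directions, against 2.08 for independent calls. Hyou1, Manf, Mlec, Sec23b and 1810074P20Rik rose with metformin and fell with restriction, and Foxo1 and Lpin2 did the reverse.

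Across 11201 genes the log2 fold changes of caloric restriction and TM5614 had a Spearman correlation of 0.409 (covariance 0.176), those of restriction and rapamycin 0.228 (covariance 0.155) and those of restriction and metformin 0.199 (covariance 0.148). Over the 8563 genes with a mean of at least 50 the Spearman correlations were 0.393, 0.199 and 0.150, and the covariances 0.0630, 0.0303 and 0.0150. Without the 10 genes listed at 0 in a group, among them pancreas genes, the covariances were 0.0841, 0.0487 and 0.0351 and the Spearman correlations 0.409, 0.227 and 0.198, so that each covariance was under 0.5 of its former size. Genes are not independent replicates, and unchanged groups of 3 libraries compared with the same controls gave 0.482 with 3 simulated control libraries and 0.318 with 6. The smallest control means are of the size that means over 3 libraries have. No simulated group had an effect, while caloric restriction changed 2232 of 11760 genes. The simulated values are therefore no threshold for those observed. With another treated group in place of the control for 1 of the effects, so that no library was shared, restriction and TM5614 gave 0.142 to 0.290 (covariance 0.00346 to 0.0437). Restriction and rapamycin gave -0.208 to 0.0527 in the same way (covariance -0.0338 to 0.00989), and restriction and metformin gave -0.290 to -0.0200 (covariance -0.0437 to -0.00616). Each of these values also holds the effect of the group used as reference. The 0.290 of TM5614 and the -0.290 of metformin are the same value with the sign turned, as both set metformin against TM5614. The -0.208 and 0.0527 of rapamycin likewise return with the sign turned for TM5614 and for metformin. These ranges are therefore not separate results for each compound. No covariance was simulated, since that needs the spread between libraries, and the controls could not be split.

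The differences between interventions were not tested directly, since that needs values per library. Rapamycin and TM5614 called 18 genes in the same direction and 2 in opposite directions, Dbp and Cobl, lowered by rapamycin and raised by TM5614. Independent calls would share 1.53 raised and 1.40 lowered genes, and give 2.93 in opposite directions. Metformin shared 5 genes with rapamycin in direction (among them Agxt and Setdb2 lowered, Hyou1 and Sec23b raised) and 6 with TM5614 (among them Agxt, Setdb2 and Srf lowered, Mlec and Saa1 raised), and called none in the opposite direction to either. Independent calls would share 0.113 raised and 0.0416 lowered genes with rapamycin, and 0.299 and 0.147 with TM5614. They would give 0.140 and 0.443 in opposite directions.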

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

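All tests in this part were chosen after the values were seen. The deposited table holds log2 fold changes for TM5441, a compound outside the labelled groups, with no group mean, dose or adjusted p. Across 11201 genes they correlated with those of TM5614 at a Spearman rho of 0.640, against 0.476 with metformin, 0.426 with rapamycin and 0.361 with caloric restriction; comparisons with a shared control correlate without any effect. Values side by side in the authors' deposited table were 3.30 for TM5614 and 2.29 for TM5441 in Saa1, -1.86 and -1.22 in G6pc, 1.86 and 0.49 in Dbp, and -0.78 and 3.33 in Rn45s. Neither the dose of TM5441 nor its number of libraries is known, and no difference between the compounds was tested, and 3 simulated control libraries shared by unchanged groups gave a rho of 0.482.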

How the results depend on the processing

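Of the settings in this part, only the threshold on the size of the log2 fold change was planned before the data were examined; all others were chosen after the result was seen. No paired analysis was possible because the table gives group means and no value per library. For the same reason the planned edgeR and DESeq2 tests, scaling by TMM and by quantiles, fits of 2 groups alone, library weights, omission of single libraries, a block for the numbers in the titles, a split of the control libraries, an estimated correlation between genes, and pseudocounts and filters on library values were not run. With a log2 fold change of at least 1 the calls were 657 for caloric restriction, 42 for rapamycin, 8 for metformin and 120 for TM5614. At an adjusted p under 0.01 they were 1396, 44, 9 and 158, and under 0.1 they were 251 for rapamycin, 34 for metformin and 775 for TM5614. With at least 0.5 of the size in the same direction also asked against the other 3 treated groups TM5614 kept 234. Among 202 pairs of a called named gene and a comparison, 17 of 606 values moved by over 1.5 times with pseudocounts of 0.5, 1 or 5. No direction turned, but the same pseudocount added to both means cannot turn one, so this is no test of direction.

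The correlation of rapamycin and caloric restriction was 0.398 as Pearson's (0.165 over genes with a mean of at least 50, 0.215 without the 10 genes at 0 in a group) and, with no shared library, 0.0279 and 0.0527 with metformin as reference but -0.0780 and -0.208 with TM5614, a change of sign. That of metformin and restriction was 0.376 as Pearson's (0.0946 and 0.176 in the same 2 ways) and negative with no shared library (-0.0200 and -0.0527 with rapamycin as reference, -0.144 and -0.290 with TM5614). That of TM5614 and restriction was smaller and kept its sign (0.142 and 0.208 with rapamycin, 0.149 and 0.290 with metformin). The values 0.208, 0.290 and 0.0527 are those of -0.208, -0.290 and -0.0527 with the sign turned. Each such pair sets the same compounds against each other in reverse order, so its values are not separate results for each compound. The values that do not return with the sign turned are 0.142 and 0.149 for TM5614, 0.0279 and -0.0780 for rapamycin, and -0.0200 and -0.144 for metformin. They are linked too, since the covariances behind 2 of them differ by that of a value that returns. They are therefore not separate results for each compound either.

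Set tests that passed with the first settings and not with another had these adjusted p from limma. With the correlation preset at 0.05 they were, under caloric restriction for drug metabolism 0.0562, cell cycle 0.124, ribosomal proteins 0.267 and pericentral hepatocytes 0.119. Under rapamycin they were, for glycolysis 0.137, amino acid breakdown 0.148, male-biased genes 0.0661, unfolded protein 0.0773, coagulation 0.137, cell cycle 0.114, erythroid cells 0.0679 and stellate cells 0.0661. Under metformin they were, for fatty acid oxidation 0.0986, ATF4 0.107, complex I 0.107 and stellate cells 0.0535. Under TM5614 they were, for ATF4 0.142, complex I 0.142 and ribosomal proteins 0.0669. With a mean of at least 50 they were, under caloric restriction for cell cycle 0.586, ribosomal proteins 0.0766 and pericentral hepatocytes 0.0948, and under rapamycin for glycolysis 0.0874 and cell cycle 0.218. With no filter they were, under caloric restriction for ribosomal proteins 0.0564 and pericentral hepatocytes 0.0555. The cell cycle list under caloric restriction had 0.0502 and 0.0554 with pseudocounts of 1 and 5. Lists that passed only with another setting were, at a mean of at least 50, under rapamycin for ribosomal proteins 0.00635, and under TM5614 for amino acid breakdown 0.0463 and unfolded protein 0.0288. Without a filter these were, under rapamycin for drug metabolism 0.0356, female-biased genes 0.0135, cholangiocytes 0.0246 and adipocytes and acinar cells 0.00231, and under metformin for female-biased genes 0.0160, and under TM5614 for cholangiocytes 0.0133 and adipocytes and acinar cells 0.0451. The adipocyte and acinar list holds pancreas genes, whose control means may come from 1 control library, as described below. Its passes can reflect that control signal.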

Other observations

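All tests in this part were chosen after the result was seen. Of 11 gene families, kept from a wider look by symbol after their values were seen, 3 are given for caloric restriction, under which 2232 of all 11760 tested genes were called. Of 20 major urinary protein genes 15 fell and none rose, and their summed means went from 203442 normalized counts in the control to 49712 (-2.03 on the log2 scale), so a shift of reads between copies leaves the fall of the family in place. Of 38 proteasome subunit genes 10 fell and none rose, with a median log2 fold change of -0.21. Of 8 sulfotransferase genes 4 rose and 1, Sult5a1, fell, and their summed means went from 3086 to 8247 normalized counts. None of the members of these families passed under metformin, and Sult1c2 fell under rapamycin and TM5614.

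The first pattern weighed is the fall of male-biased and rise of female-biased genes under caloric restriction. Female mice in that group would lower the Y-linked genes about as far as the male-biased list (median -2.82), but the median log2 fold change of Ddx3y, Uty, Kdm5d and Eif2s3y was -0.10. A control group that stands apart would leave the list near 0 against the other treated groups, where its median was -2.81. Both tests argue against these explanations. A weaker male pattern of growth hormone release under restriction, which is known to set these genes, is a candidate explanation that was not tested, since no hormone was measured.

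The second pattern is the clock genes, which differed in direction between interventions. The mean log2 level of 7 genes that peak from midday to nightfall (Dbp, Tef, Per2, Per3, Ciart, Nr1d1 and Nr1d2) minus that of 3 that peak late in the dark phase (Arntl, Clock and Nfil3) was -2.16 under rapamycin, -0.45 in the control, 0.97 under metformin, 1.20 under caloric restriction and 1.59 under TM5614. A control group that stands apart from all others would leave the 4 treated groups alike, but their range was 3.75, owing to rapamycin. Caloric restriction, metformin and TM5614 lay within 0.62 of each other with the control below all 3, so for these a control that stands apart remains a candidate explanation. In all 4 comparisons the mean levels of the arms moved in opposite directions. No clock gene was called under metformin, with no adjusted p for 5 of 19 (set test adjusted p = 0.573). The movement of the arms under metformin therefore rests on group means alone. Under caloric restriction the late arm moved little, from 7.58 to 7.36, and Nr1d1 of the other arm was called lower. Cry1, in neither arm, had a log2 fold change of 2.08 there, so the result for restriction rests on the genes chosen. Times of day or of feeding at collection that differed between groups could produce opposite movements. An effect of the interventions on the clock would do the same, and the labels give no time, so these 2 explanations cannot be told apart. Genes that follow the time of day or feeding are open to the same doubt. Cyp7a1, a gene with a daily rhythm, passed in no comparison. The doubt also bears on called genes of lipid and glucose metabolism, since the labels give no feeding state at collection.

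The third pattern is pancreas transcripts in the control mean. Acinar genes there were, among others, Amy2a5 (183), Ctrb1 (75.6) and Pnlip (48.8 normalized counts in the authors' deposited table), each listed at 0 in all 4 treated groups, while Adipoq and Plin1, markers of fat, had control means of 139 and 74.5. Of 14 acinar genes with a control mean of at least 10, 12 had control means that are whole multiples of what 1 read is worth in the same single control library, within a tolerance of 0.0001 that was narrowed from a wider one after the first result, as against 2 of 6674 other genes with control means in the range of these genes. The other 2 were Cela1 and Cela2a, whose means in the treated groups reached 93.8 (metformin) and 4.27 (rapamycin). Of the 12, Ctrl (up to 1.57, under TM5614) and Cela3b (0.321, under rapamycin) also had reads in treated groups. Pancreas tissue in 1 control library is thus a candidate explanation, and a loss of these transcripts under all treatments would need them in several control libraries, against the 85.7% found in 1. The control mean of Dmbt1, called under rapamycin and TM5614, is also a whole multiple of 1 read in a single control library. So are those of Mup17 and Fam109a, called under caloric restriction. How many called genes would match in this way without such a cause was not computed, so whether these calls rest on 1 library is not known. The calls of Cela2a and Cela1 stand beside the pancreas signal.

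Rn45s and Lars2 were high under metformin and in the TM5441 column, where their log2 fold changes were 3.33 and 3.63 in the authors' deposited table.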
